A study of Mus musculus with 54 samples.

How the data were processed

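RNA from mouse prostate tumour tissue was measured by bulk RNA sequencing of 54 libraries from 48 animals. Per the labels, total RNA was extracted with the miRNeasy Mini Kit, checked by Qubit and TapeStation, and prepared for sequencing with RiboErase depletion and the RNA HyperPrep Kit. Per the submitters' processing notes, FastQC, STAR, RSEM, limma and DESeq2 were used with the builds GRCm38 and mm10, with no versions or roles given. The deposited table holds 16772 genes by symbol, and the authors give its values in the unit log2, as log2 of a normalized count plus 1. Each value, with the logarithm and the 1 removed, was a whole multiple of one step per library, within 0.05 of a whole read for 100% of the values. The reads behind the table were recovered from that step, and 8.92% of the values were at 0. A library held 3687048 to 9741808 reads over these genes. At these depths a difference among genes with few reads rests on counting error as well as on animals. Of the 56 columns, 2 matched no sample and were left out.

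Samples were grouped by genotype, treatment and age into 11 groups. Libraries whose identifier, genotype and age were the same were taken as pieces of one animal and averaged on the log2 scale, which applied to 6 animals with 2 pieces each. The animal was the replicate in every test except the comparison of pieces within an animal.

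Differences between groups were fitted with limma 3.58.1 in R 4.3.3 on the deposited log2 values (lmFit, contrasts.fit, and eBayes with a trend of the variance on the mean). A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes with any spread in the fit. Genotypes were compared within a setting, with all groups of that setting in one fit: 12 weeks intact, intact endstage, and castrated endstage. The TKO mice given CPI1688 or vehicle had a fit of their own. All 11 groups shared one fit for comparisons between settings and for interactions, which test whether a genotype's effect differs between settings. Pieces of one animal were compared with the animal as a block. Ages and list scores were compared by exact two-sided permutation tests of the difference in means. The calls and the fits were checked on simulated data with known changes.

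A set of 32 gene lists was fixed for cell types, lineage programs, immune responses, the cell cycle, chromatin complexes and tissues that a dissection could carry along. Each list was tested with camera at a preset correlation of 0.01 and again with the correlation estimated for each list, with Benjamini-Hochberg adjustment over the lists of a comparison. The rotation test fry was run as a test of the list by itself. Members were counted by their adjusted p over all genes and, separately, adjusted over the list alone. A list score per animal is the mean over members of the log2 value centred on all animals.

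Genes were named by a rule: up to 10 of the largest log2 fold changes in each direction among the called genes, up to 4 members with the smallest adjusted p of each list described, and 29 fixed genes. The first part left out unnamed gene models, immunoglobulin and T cell receptor segments, and genes in the lowest 25% by mean value. The groups, comparisons, lists, naming rule and the alternatives listed next were set before the data were examined. Gene positions come from GENCODE release M21 on GRCm38, which held 99.9% of the symbols.

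The alternatives set then left out the lowest 25% of genes by mean value, raised the offset on the log scale, normalized by quantiles, weighted samples, changed the groups in the fit, added age or the letters of the animal identifier as a covariate, treated pieces of an animal differently, and left out each animal of a group of 2 to 5 in turn. Alternatives chosen after seeing the data were limma-voom on the recovered reads, left-out or adjusted libraries with much Lars2 or Ttn, adjustment for fibroblast or adipocyte list scores, leaving out each of the 8 intact endstage DKO_EE animals, and mean list changes without animals far from their group. Figures and permutation tests used Python 3.11.15 with scipy 1.17.1, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The SKO model that the series description names was not analysed here.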

Results

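Gene expression was measured in prostate tumour tissue of mice with engineered tumours (DKO and TKO models) and of DKO mice described by the submitters as carrying Ezh2 deletions (DKO_EE and DKO_EP). The labels say neither what EE and EP stand for nor which exons or alleles are deleted. Ezh2 encodes the catalytic subunit of Polycomb repressive complex 2, which methylates histone H3 and silences developmental genes. Intact mice were sampled at 12 weeks, with 4 animals each of DKO, DKO_EE and DKO_EP, and at endstage, with 3 DKO, 8 DKO_EE and 3 DKO_EP animals. Mice castrated at 12 weeks were sampled at endstage, with 4 DKO, 5 DKO_EE and 5 DKO_EP animals. Castrated TKO mice received vehicle or CPI1688, an Ezh2 inhibitor per the labels, with 4 animals each. Libraries held 3687048 to 9741808 reads over the genes of the table.

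Ezh2 (chromosome 6, 47530139 to 47595341, GRCm38) was measured first as a check of the labels, and the transcript was detected in every group. At intact endstage the mean log2 value was 9.61 ± 0.23 in DKO (SD, n = 3), 8.28 ± 0.49 in DKO_EE (SD, n = 8) and 9.39 ± 0.11 in DKO_EP (SD, n = 3). At castrated endstage it was 9.36 ± 0.62 in DKO (SD, n = 4), 8.46 ± 0.47 in DKO_EE (SD, n = 5) and 9.17 ± 0.33 in DKO_EP (SD, n = 5). At 12 weeks it was 8.40 ± 0.22 in DKO, 7.60 ± 0.20 in DKO_EE and 8.22 ± 0.36 in DKO_EP (SD, n = 4 each). In castrated TKO tumours it was 9.45 ± 0.73 with vehicle and 9.85 ± 0.35 with CPI1688 (SD, n = 4 each). By limma, Ezh2 was lower in DKO_EE than in DKO by a log2 fold change of -1.34 at intact endstage (SE 0.26, adjusted p = 0.0194). The log2 fold changes of -0.90 at castrated endstage (SE 0.30, adjusted p = 0.0831) and -0.80 at 12 weeks (SE 0.19, adjusted p = 0.975) did not pass the test over all genes. At 12 weeks the animals did not overlap, at 7.33 to 7.79 in DKO_EE and 8.19 to 8.69 in DKO. Nor did they at intact endstage (7.41 to 8.76 and 9.47 to 9.88), while at castrated endstage they did (8.02 to 9.19 and 8.43 to 9.71). Between DKO_EP and DKO the log2 fold changes were -0.18 at 12 weeks, -0.22 at intact endstage and -0.19 at castrated endstage, none past the test, so the DKO_EP values lay near those of DKO. The intact call was lost without DKO replicate 1, 2 or 3 (adjusted p = 0.104, 0.0553 and 0.0701), with age as a covariate (0.0683), with Lars2 as a covariate (log2 fold change -1.07, 0.184), with only the libraries under 10% Lars2 (0.0548) and with the first library of each animal (0.0878), while no single DKO_EE animal ended it. The castrated difference passed without DKO replicate 2 (log2 fold change -1.21, adjusted p = 0.00921) and without DKO_EE replicate 2 (-1.08, adjusted p = 0.0471). It passed as well with all 11 groups in one fit and with array weights. A gene-level value counts reads from all exons, so a deletion of some exons would be understated by it.

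**Figure D1:**
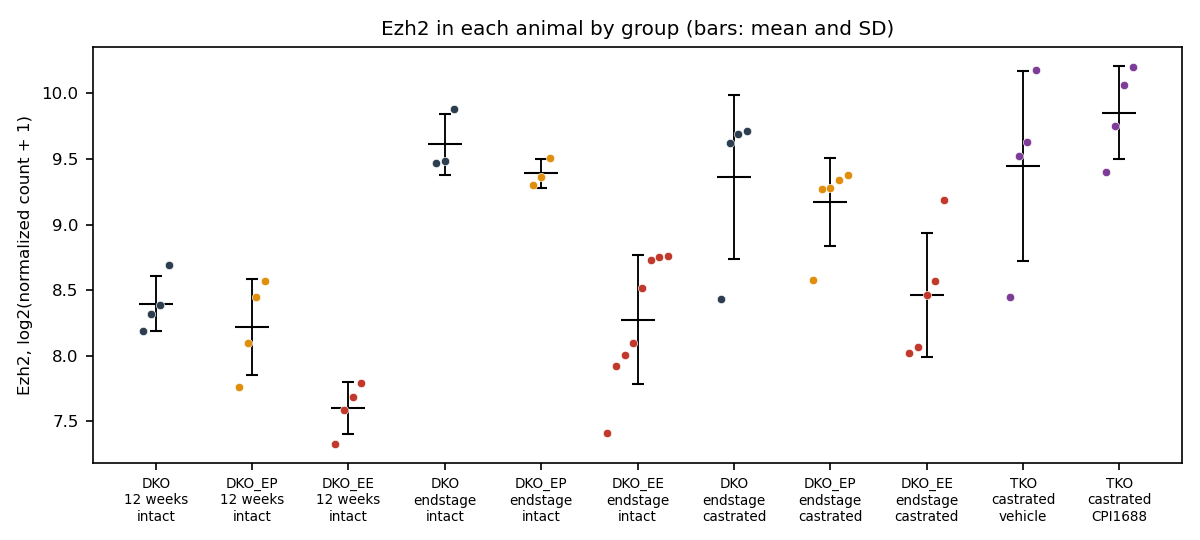
Log2 value of Ezh2 (normalized count plus 1) in each animal of the 11 groups, with the group mean and SD. The DKO_EE means lie below those of DKO in each setting, at 8.28 against 9.61 at intact endstage, 8.46 against 9.36 at castrated endstage and 7.60 against 8.40 at 12 weeks.

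DKO tumours at intact endstage were compared with DKO prostates at 12 weeks to describe tumour progression. Neuroendocrine genes rose: 28 of 39 members were higher and 1 was lower (30 and 1 adjusted over the list alone). Chga, which encodes the secretory granule protein chromogranin A (chromosome 12, 102554969 to 102565028), rose from 3.95 ± 1.55 (SD, n = 4) to 10.71 ± 0.59 (SD, n = 3), by 6.76 on the log2 scale (SE 1.17, adjusted p = 2.54e-05), and Foxa2, a forkhead factor of neuroendocrine prostate tumours, by 7.70 (SE 1.06, adjusted p = 8.49e-07). Cell division genes rose as well, with 30 of 30 proliferation genes and 33 of 33 E2F target and DNA replication genes higher by either adjustment. Among them were the kinase gene Cdk1 at 3.28 (SE 0.37, adjusted p = 6.72e-08) and Mki67 at 3.13. The camera test called the neuroendocrine list (adjusted p = 2.21e-10) and the proliferation list (2.55e-28), and both calls were lost at adjusted p = 0.436 and adjusted p = 0.163 with an estimated correlation.

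Many listed genes of the prostate epithelium and its surroundings fell over the same interval. The androgen response list had 15 of 29 members lower and 2 higher (16 and 2 adjusted over the list alone; adjusted p = 0.000218, and adjusted p = 0.163 with an estimated correlation). Slc45a3, a prostate-specific transporter gene, changed by -5.56 and the homeobox gene Hoxb13 by -4.80. Pbsn (probasin, chromosome X, 77837901 to 77853623) and Msmb, both androgen-regulated secretory genes, had mean log2 values of 6.65 and 6.60 at 12 weeks and were listed at 0 in every DKO endstage library. Lower members numbered 14 of 22 on the luminal epithelium list (15 adjusted over the list alone; adjusted p = 0.366 with an estimated correlation) and 13 of 22 on the basal epithelium list, where Jag2 rose by 1.76 (15 and 1 adjusted over the list alone; adjusted p = 0.529 with an estimated correlation). They numbered 12 of 20 seminal vesicle and secretory genes, 13 of 17 smooth muscle genes and 17 of 17 skeletal muscle genes (13, 16 and 17 adjusted over the list alone), with adjusted p = 0.404, 0.461 and 0.404 with an estimated correlation. Skeletal muscle RNA varied among the 12-week libraries, where Ttn, the titin gene, took 0.113 to 2.551% of the reads in DKO, against 0.027% at most in DKO at endstage.

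Members of immune and developmental lists were called over the same interval, in a comparison where many genes changed. Interferon response genes were lower for 18 of 34 members (20 adjusted over the list alone), with Oas3 at -3.10, and class I antigen presentation genes for 12 of 18 (15 adjusted over the list alone), with Tapbp at -2.14 and B2m at -2.33. Both list calls were lost at adjusted p = 0.461 with an estimated correlation. Hox cluster genes, which set position along the body axis, were lower for 18 of 35 members by either adjustment (adjusted p = 0.461 with an estimated correlation). Developmental factors under Polycomb control included 20 lower and 5 higher members of 68 by either adjustment, and camera gave an adjusted p of 0.0828. Ezh2 itself rose by 1.21 (SE 0.32, adjusted p = 0.00302), and other Polycomb repressive complex 2 genes included 5 higher and 2 lower of 10 by either adjustment, such as Suz12 at 0.86 and Ezh1 at -0.66. Of all 16772 genes tested by limma, 3023 were higher and 3140 lower.

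At 12 weeks, the comparison asked whether early tissue differs between the Ezh2 genotypes. No gene of 16626 passed in DKO_EE against DKO, in DKO_EP against DKO or in DKO_EE against DKO_EP with limma on the log2 values or with limma-voom, while 796, 449 and 593 genes had an unadjusted p under 0.05. Probasin was one of the larger differences, with a mean Pbsn log2 value of 0.81 ± 1.05 in DKO_EE, 4.04 ± 2.80 in DKO_EP and 6.65 ± 2.20 in DKO (SD, n = 4 each). Chga had mean log2 values of 5.99 ± 1.49 in DKO_EE and 3.95 ± 1.55 in DKO (SD, n = 4 each). In DKO_EE, all 17 skeletal muscle genes were lower and 14 of 30 proliferation genes higher when adjusted over the list alone, none over all genes, and camera's adjusted p was 0.447 for each with an estimated correlation. For DKO_EP, 6 of 16 adipocyte genes were lower adjusted over the list alone and 0 over all genes (adjusted p = 2.52e-15, and adjusted p = 0.0703 with an estimated correlation). DKO replicate 4 moved the first 2 counts: 5 genes passed in DKO_EE and 5 in DKO_EP without it. It is the only 12-week DKO animal with the identifier letters of the DKO_EE and DKO_EP animals, so without it the letters and the genotype coincide. With all 11 groups in one fit, 84 genes passed in DKO_EE, 4 in DKO_EP and 1 between DKO_EE and DKO_EP, and in animals with Ttn under 1% of reads, 10 passed in DKO_EE and 6 in DKO_EP. Under the Ttn limit only DKO replicates 2 and 3 and DKO_EP replicates 1 and 3 remained beside DKO_EE, so the letters and the genotype coincided there too.

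The question at intact endstage was whether tumours that form without castration differ between the Ezh2 genotypes. In DKO_EE against DKO (n = 8 and 3), limma called 187 genes higher and 90 lower of 16640, of which 136 and 77 by more than 2-fold. Fign, a microtubule-severing ATPase gene, rose by 4.07 (SE 0.35, adjusted p = 8.47e-05). Chn1, a Rac GTPase-activating protein gene, rose by 3.74 (SE 0.42, adjusted p = 0.000732), and Skap1, a T cell adaptor gene, by 5.59 (SE 0.93, adjusted p = 0.0105). Lhx2, a LIM homeobox factor, was lower at -4.77 (SE 0.46, adjusted p = 0.000164), as were Dpp10, a subunit gene of potassium channels, at -7.92 (SE 1.28, adjusted p = 0.00832) and Onecut2, a homeobox factor of aggressive prostate cancer, at -5.28 (SE 0.96, adjusted p = 0.0155). Rybp, a Polycomb repressive complex 1 gene, was lower at -1.15 (SE 0.26, adjusted p = 0.0393), the only one of 19 on its list by either adjustment.

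Neuroendocrine expression was present in the intact DKO_EE tumours: Chga reached 11.54 ± 0.29 (SD, n = 8) against 10.71 ± 0.59 in DKO (SD, n = 3). Of 38 neuroendocrine genes, 1 was lower, the synaptic gene Snap25 at -1.13 (SE 0.16, adjusted p = 0.00476), and 0 higher, against 1 lower and 3 higher adjusted over the list alone. Interferon response genes were higher for 9 of 34 members (22 adjusted over the list alone), with the antiviral gene Oas2 at 2.13 (SE 0.39, adjusted p = 0.0172). Camera called the interferon list (adjusted p = 1.49e-12), a call lost at adjusted p = 0.637 with an estimated correlation. Macrophage genes included 2 lower members of 18, Adgre1 at -1.46 and Lyz2 at -1.42 (2 adjusted over the list alone). Class I antigen presentation genes included 1 higher of 17, H2-D1 at 0.99 (6 adjusted over the list alone). The 16 adipocyte genes had no member past the test over all genes, and 9 lower and 1 higher adjusted over the list alone. Each of these 3 lists lost its call at adjusted p = 0.761 with an estimated correlation. The mitochondrial leucyl-tRNA synthetase gene Lars2 (chromosome 9, 123366927 to 123462666) took over 10% of the reads in 5 of the 12 DKO_EE and 5 of the 5 DKO_EP intact libraries, and at most 0.026% in DKO.

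The count of 277 moved with single animals of both groups. It was 74, 121 and 64 without DKO replicate 1, 2 and 3, and from 134 (without DKO_EE replicate 5_6) to 590 (without replicate 4) when DKO_EE animals were left out. Onecut2 and Rybp lost their calls without any one of the DKO animals (highest adjusted p 0.0913 and 0.164), Dpp10 without replicate 1 (adjusted p = 0.0599), Skap1 without replicate 1 or 3 (0.0651 and 0.0683) and Oas2 without the same animals (0.0919 and 0.0978), while Fign, Chn1, Lhx2 and Snap25 passed without any single animal of either group. Rybp also lost its call without 6 of the 8 DKO_EE animals (adjusted p up to 0.0696, without replicate 2). With age as a covariate 81 genes passed, with Lars2 as a covariate 6, with only the libraries under 10% Lars2 94, with the first library of each animal 116 and with array weights 1308. The split was 157 higher and 171 lower with limma-voom.

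Castrated endstage tumours addressed the same question after androgen withdrawal. In DKO_EE against DKO (n = 5 and 4), 566 genes were higher and 712 lower of 16558, of which 373 and 589 by more than 2-fold. Among the higher genes, Nefl and Nefm, which encode neurofilament proteins, rose by 11.84 (SE 1.61, adjusted p = 0.00126) and 9.64 (SE 1.39, adjusted p = 0.00181), and the protocadherin gene Pcdh10 rose by 9.07 (SE 1.22, adjusted p = 0.00119). Nefl was at 0 in 3 of the 4 castrated DKO animals and had a mean of 11.40 in intact DKO, and at intact endstage it did not differ between DKO_EE and DKO by the test (log2 fold change -1.55, SE 1.63, adjusted p = 0.679), nor did Nefm (0.30, SE 1.42, adjusted p = 0.939). Among the lower genes, Onecut2 changed by -8.56 (SE 0.66, adjusted p = 1.46e-05) and Dpp10 by -6.82 (SE 1.63, adjusted p = 0.0244), a call lost without DKO_EE replicate 1 (adjusted p = 0.0573), DKO replicate 1 (0.0681) or DKO replicate 4 (0.0636) and with limma-voom (0.28). Sim2, a bHLH-PAS factor, had a mean log2 value of 7.21 in DKO and was listed at 0 in every castrated DKO_EE library.

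Some fibroblast, T and NK cell, and class II antigen presentation genes were lower in the castrated DKO_EE tumours. The fibroblast list had 11 of 24 members lower (22 adjusted over the list alone), including the surface marker Thy1 at -2.66 (SE 0.42, adjusted p = 0.00312) and the matrix proteoglycan genes Lum at -3.97 and Dcn at -3.25. T and NK cell genes were lower for 6 of 21 (7 adjusted over the list alone), with the co-receptor gene Cd8a at -2.80 (SE 0.52, adjusted p = 0.00769). Class II antigen presentation genes were lower for 5 of 12 (10 adjusted over the list alone), with Cd74, the invariant chain, at -2.12. Camera's adjusted p was 5.24e-13, 2.73e-05 and 1.56e-06 for the 3 lists, and adjusted p = 0.284, 0.544 and 0.511 with an estimated correlation. Developmental factors under Polycomb control had 8 lower and 2 higher members of 63 (15 and 3 adjusted over the list alone), with Gata3 at -3.01 (SE 0.46, adjusted p = 0.00263), Foxf1 at -3.33, Bmp2 at -2.28 and Lhx2 at -3.82. This list alone, of 640 list tests, kept its camera call with an estimated correlation (adjusted p = 0.000174, and adjusted p = 0.0301 with an estimated correlation), while it lost it when the lowest 25% of genes by mean value were left out (0.115) and without the 99-week DKO animal (0.137, with a mean change of -1.02 against -1.05 before). The preset correlation gave 213 calls over the same 640 tests.

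Other groups in the castrated DKO_EE tumours went both ways or held few called genes. The androgen response list had 3 higher and 4 lower members of 26 (3 and 5 adjusted over the list alone), with the retinoic acid enzyme gene Aldh1a3 at -4.15 (SE 0.87, adjusted p = 0.0147). Factors of epithelial-mesenchymal transition had 4 lower and 1 higher of 21 (10 and 4 adjusted over the list alone; adjusted p = 0.6 with an estimated correlation), with Zeb1 at -1.46 (SE 0.28, adjusted p = 0.00936). Lineage plasticity factors had 3 lower and 1 higher of 20 (5 and 1 adjusted over the list alone), with Sox9 at -4.04 and Mycl at 1.96, and their mean change was -0.55 while their median was 0.03. Basal epithelium genes were lower for 3 of 22 by either adjustment, with Dst at -1.48, and tuft cell genes for 1 of 20, Dclk1 at -1.84 (adjusted p = 0.6 and 0.564 with an estimated correlation). Neuroendocrine genes had 1 higher of 38, Hes6 at 1.96 (0 adjusted over the list alone). Their camera adjusted p was 0.000252, and 0.689 with an estimated correlation. Chga was 10.85 ± 0.48 in DKO_EE (SD, n = 5) and 8.68 ± 3.40 in DKO (SD, n = 4), where replicate 2 was an animal of 99 weeks. Without that animal the mean change of the neuroendocrine list went from 1.49 to 0 (camera adjusted p = 0.801). That of the basal list went from -1.89 to -0.42 (0.203). With age as a covariate the neuroendocrine list turned downward and was not called (camera adjusted p = 0.738).

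The remaining lists of this comparison had few called members. Over all genes, single members or none were called among squamous differentiation, luminal epithelium, endothelium, smooth muscle, skeletal muscle, macrophage, neutrophil, B and plasma cell, interferon response, proliferation, adipocyte, erythroid, and seminal vesicle genes, and among the Polycomb repressive complex 1 and 2 genes. Of these, camera called proliferation upward (adjusted p = 5.25e-07, and 0.00205 without the 99-week DKO animal, where the mean change went from 0.96 to 0.25) and endothelium, B and plasma cells and smooth muscle downward (0.00415, 0.00949 and 0.0197, and without the 99-week animal 0.00942, 0.0265 and 0.0881, so that the smooth muscle call was lost), each at adjusted p = 0.6 with an estimated correlation. E2F target genes had 2 higher of 33 (3 adjusted over the list alone; adjusted p = 4.8e-07, and 0.00523 without the 99-week animal) and hypoxia and glycolysis genes 2 higher of 20 by either adjustment (adjusted p = 0.0171), both at adjusted p = 0.6 with an estimated correlation. The nerve and glia list had 2 higher of 18, Nefl and Nefm (2 higher and 2 lower adjusted over the list alone), with a mean change of 0.75, a median of -0.13 and a downward test (adjusted p = 0.966). The gastrointestinal list had 1 lower and 1 higher member of 24, the higher being Lgr5 at 4.59 (3 and 1 adjusted over the list alone; adjusted p = 0.00634, adjusted p = 0.6 with an estimated correlation, and adjusted p = 0.238 without the 99-week animal). Cell cycle inhibitors had 2 lower of 22 and class I antigen presentation 3 lower of 18, by either adjustment.

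The castrated count of 1278 was 780, 829 and 787 without DKO_EE replicate 1, 2 and 5, 783 without DKO replicate 1, and 1443 without DKO replicate 2. It was 454 with age as a covariate, 473 with only the 2 groups in the fit and 2407 with array weights. The call of Aldh1a3 was lost with age as a covariate (log2 fold change -3.96, adjusted p = 0.0768) and with only the 2 groups (-4.15, adjusted p = 0.0621).

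Genes called in both endstage settings were counted, a test chosen after seeing the data. In the same direction, 57 genes were higher and 23 lower in DKO_EE than in DKO in intact and in castrated tumours, where 6.42 and 3.88 would be shared if the calls were independent (one-sided Fisher's exact test, p = 2.02e-38 and 2.9e-12, over 16479 genes), and 0 went opposite ways. The animals of the settings differ, but genes are not independent of one another. The 80 shared genes include Fign, Skap1, Dpp10, Onecut2, Lhx2 and Rybp. Their number was 22 with age as a covariate, 33 with only the 2 groups in each fit, 519 with array weights, and 29, 31, 26 and 49 without intact DKO replicate 1, 2, 3 and castrated DKO replicate 1. Without single intact DKO_EE animals it was 46 (replicate 5_6) to 144 (replicate 4).

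**Figure D2:**
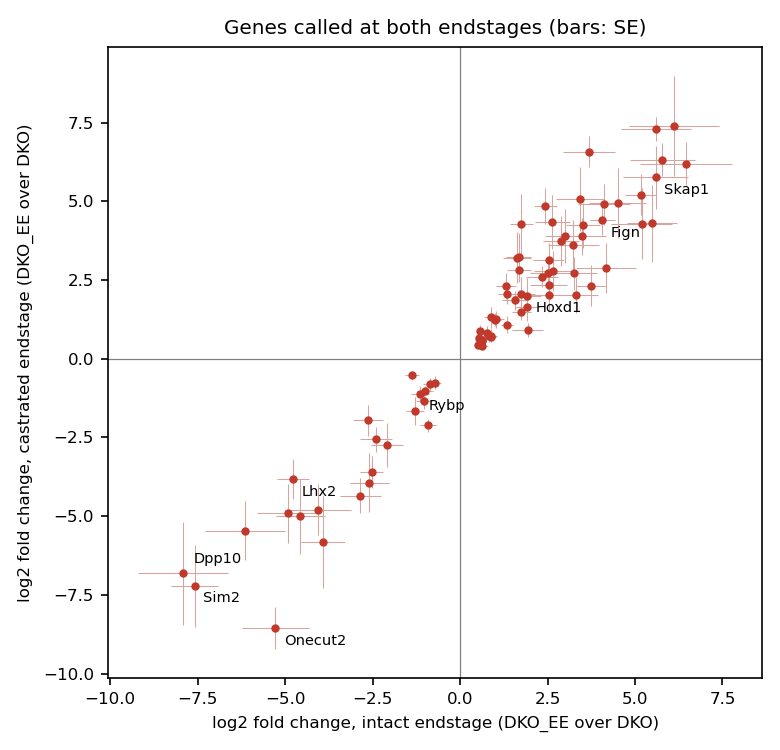
Log2 fold change of DKO_EE against DKO at intact endstage (horizontal) and castrated endstage (vertical) for the 80 genes called in both, with standard errors. All 57 higher genes lie in the upper right and all 23 lower genes in the lower left.

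Within the Hox clusters, 4 of 35 genes were higher in castrated DKO_EE tumours than in DKO (5 adjusted over the list alone), and all 4 lie in the Hoxd cluster on chromosome 2. Hoxd8 (74704615 to 74707933) rose by 4.33 (SE 0.60, adjusted p = 0.00137), Hoxd3 by 3.24 (adjusted p = 0.00887), Hoxd9 by 2.62 (adjusted p = 0.0454) and Hoxd1 by 2.0 (SE 0.56, adjusted p = 0.0461). The neighbouring Hoxd10 to Hoxd13 had log2 fold changes of -1.57, -0.85, -1.62 and -3.86, none past the test. In castrated DKO_EP tumours, Hoxd8, Hoxd3 and Hoxd9 lay above DKO as well, by 2.89 (SE 0.60, adjusted p = 0.118), 2.21 (SE 0.62, adjusted p = 0.185) and 2.11 (SE 0.73, adjusted p = 0.244), none past the test, and Hoxd1 by 0.24. The Hoxd8 difference of DKO_EP passed with array weights (adjusted p = 0.00516) and without DKO replicate 2 or 3 (0.012 and 0.0417). Between castrated DKO_EE and DKO_EP, Hoxd8 did not pass (1.45, SE 0.56, adjusted p = 0.29), while it passed with array weights (0.0212), with only the 2 groups (0.00311) and with limma-voom (0.0305), so whether the rise is particular to DKO_EE stays open. The list as a whole was not called by camera (adjusted p = 0.558). The transcripts annotated for Hoxd3 and Hoxd4 overlap, so reads can be assigned to either. The calls of Hoxd9 and Hoxd1 were lost with limma-voom (adjusted p = 0.0508 and 0.051), while their values stayed at 2.67 and 2.41. They were lost as well when most single animals were left out, with adjusted p up to 0.103 for Hoxd9 without DKO_EE replicate 1 and 0.111 for Hoxd1 without DKO replicate 1. At intact endstage Hoxd1 was listed at 0 in every DKO library and had a mean log2 value of 1.92 in DKO_EE (adjusted p = 0.0313, lost without any of the 3 DKO animals at up to 0.118, without replicate 3, and without DKO_EE replicate 5_6 or 7_8 at 0.0553 and 0.0535).

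**Figure D3:**
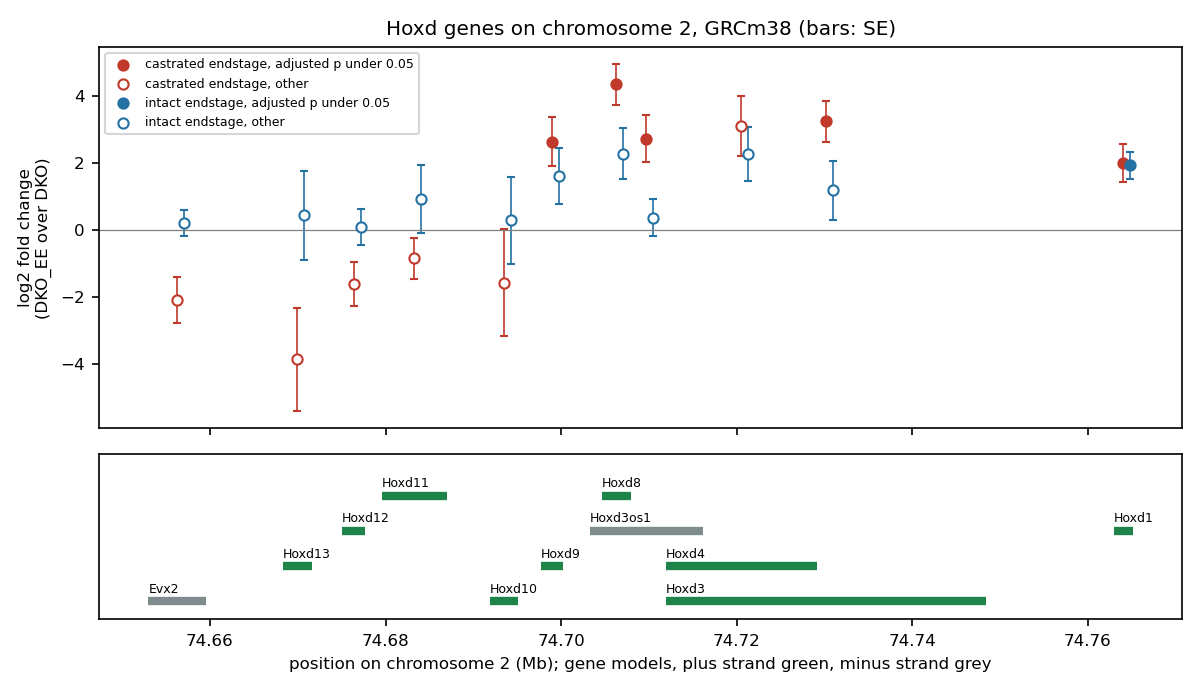
Log2 fold change of DKO_EE against DKO, with standard errors, along the Hoxd cluster of chromosome 2 in Mb, for castrated and intact endstage. In castrated tumours the genes from Hoxd9 to Hoxd1 lie above 0, at 2.62 to 4.33 for Hoxd9 and Hoxd8, and those from Hoxd13 to Hoxd10 below 0.

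DKO_EE and DKO_EP were compared with each other in each setting. At intact endstage, 164 genes were higher and 107 lower in DKO_EE than in DKO_EP (n = 8 and 3), with a split of 130 and 133 under a larger offset and of 55 and 156 with limma-voom. Fign rose by 5.41 (SE 0.35, adjusted p = 4.78e-06), Skap1 by 6.79 (SE 0.93, adjusted p = 0.00305) and Cacna1d, a calcium channel gene, by 5.16 (SE 0.49, adjusted p = 0.000176). Lhx2 was lower at -4.50 (SE 0.46, adjusted p = 0.000342) and the carbonic anhydrase gene Car4 at -5.79 (SE 0.89, adjusted p = 0.00547). Ezh2 was lower at -1.12 (adjusted p = 0.0408), a call lost without DKO_EP replicate 1_2 (the animal with libraries 1 and 2; adjusted p = 0.135) or either other DKO_EP animal, and without DKO_EE replicate 1, 7_8 or 11_12 (0.0699, 0.0712 and 0.0603). That call was also lost with only the 2 groups (0.0583), age (0.39) or Lars2 (0.0595) as a covariate, the first library of each animal (0.117) and only the libraries over 10% Lars2 (0.0959). Interferon response genes were higher for 3 of 34 (13 adjusted over the list alone, where 1 was lower; adjusted p = 0.796 with an estimated correlation). Developmental factors under Polycomb control were lower for 3 of 66 (11, and 1 higher, adjusted over the list alone; adjusted p = 0.698 with an estimated correlation). The count of 271 was 168, 91 and 47 without DKO_EP replicate 1_2, 3_4 and 5, 175 to 602 without single DKO_EE animals (175 without replicate 5_6, 602 without replicate 3), 16 with age as a covariate and 1430 with array weights. Lars2 took over 10% of the reads in all 5 DKO_EP libraries, and the count was 171 with Lars2 as a covariate, 118 in libraries over 10% Lars2 and 571 with all libraries and duplicateCorrelation.

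At castrated endstage, 117 genes were higher and 164 lower in DKO_EE than in DKO_EP (n = 5 each). Fign was higher by 6.07 (SE 0.44, adjusted p = 8.54e-06), Skap1 by 5.42 (SE 0.94, adjusted p = 0.0101) and Ntn1, the axon guidance gene netrin 1, by 4.83 (SE 0.59, adjusted p = 0.000832). Onecut2 was lower at -7.22 (SE 0.62, adjusted p = 4.33e-05) and Bmp2, a bone morphogenetic protein gene, at -3.82 (SE 0.35, adjusted p = 7.91e-05). Lineage plasticity factors had 3 lower members of 20, Onecut2, Lhx2 at -5.19 and Sox4 at -1.27 (3 and 1 higher adjusted over the list alone; camera adjusted p = 0.103). No neuroendocrine gene of 38 passed by either adjustment (adjusted p = 0.773). No fibroblast gene passed by either adjustment, while camera called the list downward (adjusted p = 3.01e-05, and adjusted p = 0.974 with an estimated correlation). The count of 281 was 181 without DKO_EE replicate 3, 180, 167 and 166 without DKO_EP replicate 1, 2 and 3, 787 with only the 2 groups and 1079 with array weights.

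DKO_EP was also compared with DKO. At intact endstage no gene of 16640 passed with limma or limma-voom (n = 3 each), and 965 had an unadjusted p under 0.05. One gene passed without DKO replicate 3, and 26 with array weights. Chga was 11.37 ± 0.19 in DKO_EP (SD, n = 3), and no neuroendocrine gene passed by either adjustment (adjusted p = 0.000152, and adjusted p = 0.32 with an estimated correlation). At castrated endstage 3 genes were higher and 2 lower of 16558 (n = 5 and 4), with a split of 4 and 5 under a larger offset and of 5 and 2 after quantile normalization. Slc38a11, an amino acid transporter family gene, rose by 4.82 (SE 0.60, adjusted p = 0.00675), Ccdc114, a ciliary dynein docking gene, by 4.19 (SE 0.49, adjusted p = 0.00458) and Zkscan2, a zinc finger gene, by 4.16 (SE 0.44, adjusted p = 0.00192). Traf3, a signalling adaptor gene, was lower at -0.75 (SE 0.11, adjusted p = 0.0242), a call lost without DKO_EP replicate 2, 3, 4 or 5 or DKO replicate 4 (adjusted p up to 0.0928, without DKO_EP replicate 5). The other lower gene, Pdcd1, which encodes a checkpoint receptor of T cells, had a mean log2 value of 3.33 in DKO and was listed at 0 in every castrated DKO_EP library (adjusted p = 0.00192), and it was named after its values were seen. Fibroblast, T and NK cell, and class II genes had 0 members past the test over all genes and 11, 13 and 8 lower adjusted over the list alone. Their camera adjusted p was 1.16e-08, 1.16e-08 and 7.2e-08, and adjusted p = 0.386, 0.349 and 0.349 with an estimated correlation. The count of 5 was 10, 15, 67 and 9 without DKO replicate 1, 2, 3 and 4, 0 with age as a covariate or with only the 2 groups, 2 with limma-voom and 57 with array weights.

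Castrated and intact endstage tumours of one genotype were compared to ask how androgen withdrawal altered them. In DKO 1176 genes were higher and 1162 lower in castrated tumours, in DKO_EE 1392 and 1374, and in DKO_EP 820 and 836 of 16772. The beta-globin gene Hbb-bs rose by 6.0 in DKO (SE 1.12, adjusted p = 9.87e-05), and Polycomb repressive complex 1 genes had 7 higher and 1 lower of 19 by either adjustment, with Pcgf2 at 1.58 (adjusted p = 0.987 with an estimated correlation). Proliferation genes were lower in castrated DKO tumours for 12 of 30 (26 adjusted over the list alone; adjusted p = 0.987 with an estimated correlation), with Kif11 at -2.05. Without the 99-week animal 1 of 30 was lower, and the mean change of the list went from -1.09 to -0.39 (adjusted p = 0.0328). The erythroid list had 3 higher members of 8 in DKO, Hba-a1, Hbb-bs and Hbb-bt, with a mean change of 0.80 and a median of -0.84. Hba-a1 was listed at 0 in every intact library and at 2.05 to 10.29 in the castrated ones, TKO included. Hbb-bs had a median log2 value of 0.0 in the intact libraries and 8.0 in the castrated ones. The globin rises thus cannot be told apart from the split of the libraries given next. These settings also differed in Rmrp and in other single genes. Rmrp, the RNA of a mitochondrial ribonuclease (chromosome 4), had log2 values of 12.54 to 15.11 in all 32 intact libraries and of 6.21 to 7.91 in all 22 castrated ones, TKO included. With 10 reads or more asked for, 20 genes were present in every intact library and at 0 in every castrated one, such as Mrgpra6, Ado and Atp5o. Of 1109 genes called in the same direction in all 3 genotypes, 393 did not overlap between any intact and any castrated library. No castrated and intact libraries shared an Rmrp range, so the treatment and this difference cannot be separated over the genes as a whole. The DKO count was 990 with only the 2 groups in the fit and 3679 with array weights.

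**Figure D4:**
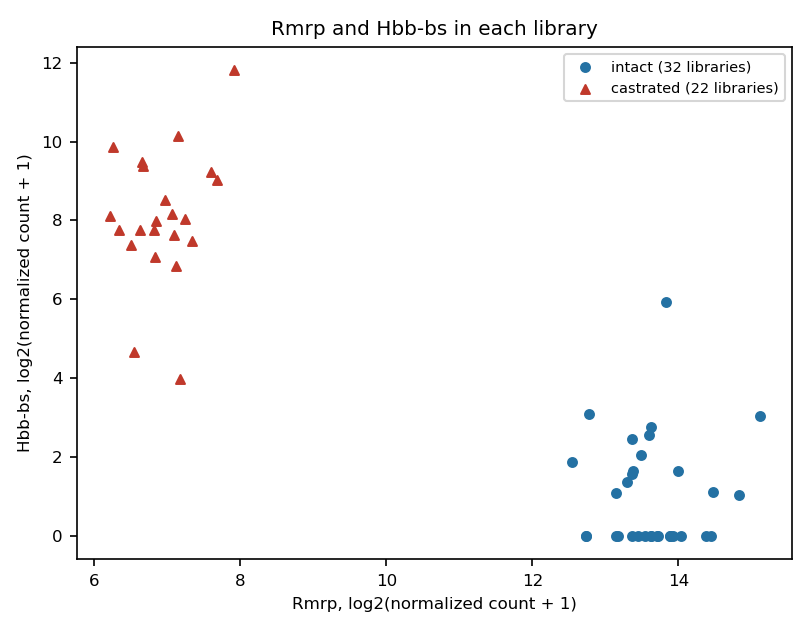
Log2 values of Rmrp (horizontal) and Hbb-bs (vertical) in each of the 54 libraries. The 32 intact libraries lie at 12.54 or more for Rmrp and the 22 castrated libraries at 7.91 or less.

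Interaction tests asked whether an Ezh2 genotype's effect differed between settings. For DKO_EE the effect at intact endstage differed from that at 12 weeks for 16 genes upward and 5 downward. Lhx2 differed by -5.96 (adjusted p = 0.000601), with mean log2 values at 12 weeks of 1.78 in DKO_EE and 0.58 in DKO, and at intact endstage of 0.23 and 5.0. Fign differed by 4.07 (adjusted p = 0.000627), Rora, a nuclear receptor gene, by 2.11 (SE 0.36, adjusted p = 0.0021), and Marcks, a protein kinase C substrate gene, by -1.83 (SE 0.30, adjusted p = 0.00144). Lars2 differed by 7.84 for DKO_EE and 12.06 for DKO_EP, where it was the 1 gene called. Its share of the reads differed between pieces of one animal. It was 18.734% in the DP piece and 0.534% in the AP piece of DKO_EE replicate 7_8. In replicate 11_12 it was 0.009% in the DP-LP piece and 18.955% in the AP piece. Both pieces were high in replicate 5_6 and both low in replicate 9_10. The Lars2 interactions therefore cannot be read as an effect of the genotype. Between castrated and intact endstage, the DKO_EE effect differed for 2 genes, the histone gene Hist1h4m at 6.20 (SE 1.03, adjusted p = 0.00803) and the ciliary gene Cfap69 at 3.28 (SE 0.63, adjusted p = 0.0445). The DKO_EP effect differed for 4, Hist1h4m at 5.79, Cfap69 at 3.51, Lars2 at -10.49 and Traf3 at -1.27. Both tests use the same castrated and intact DKO animals. The like values of Hist1h4m and Cfap69 thus do not tell an effect of each Ezh2 genotype from a difference within DKO. The DKO_EE count against 12 weeks was 42 without 12-week DKO replicate 4 and 51 without intact DKO_EE replicate 3, and the DKO_EP count 3 without it. The count of 2 moved between 0 and 5 and that of 4 between 0 and 4 when single animals were left out, reaching 0 for DKO_EE without castrated DKO replicate 3 or intact DKO replicate 1 and 0 for DKO_EP without intact DKO_EP replicate 1_2 or intact DKO replicate 1, and limma-voom gave 0 for DKO_EP.

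CPI1688 was compared with vehicle in castrated TKO mice to test an Ezh2 inhibitor. No gene of 16512 passed with limma or limma-voom (n = 4 each), the smallest adjusted p was 1, and 337 genes had an unadjusted p under 0.05. In simulated changes at this sample size, 26.9% of 2-fold, 61.2% of 4-fold and 72.7% of 8-fold changes were recovered. The simulation changed only genes above a minimum mean count and drew each gene independently. Recovery may thus be lower for genes with few reads or where genes move together. Hox cluster genes had a mean change of 1.19, neuroendocrine genes of 1.08 and squamous differentiation genes of -1.33, with 0 members past the test by either adjustment. Camera called the 3 lists (adjusted p = 2.32e-09, 7.75e-07 and 9.93e-08), with adjusted p = 0.569, 0.774 and 0.711 with an estimated correlation. Without vehicle replicate 1 the mean change of the neuroendocrine list went from 1.08 to 0.06 and its median to -0.27, with camera downward and not called (adjusted p = 0.458), and the mean change of the squamous list went from -1.33 to -0.56 (adjusted p = 0.0177).

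TKO tumours given vehicle were compared with castrated DKO tumours to describe how the models differ. Trp53, the p53 tumour suppressor gene, which the labels do not name as deleted (chromosome 11, 69580359 to 69591873), was lower at -1.97 (SE 0.25, adjusted p = 1.23e-05), with 6.71 ± 0.83 in TKO and 8.68 ± 0.31 in DKO (SD, n = 4 each). Of 16772 genes, 51 were higher and 44 lower. Pcdh10 rose by 7.95 (SE 1.35, adjusted p = 0.00136) and Slc38a11 by 6.06 (SE 0.98, adjusted p = 0.000688), while Pnp2, a purine nucleoside phosphorylase gene, was lower at -3.17 (SE 0.54, adjusted p = 0.00155). T and NK cell genes had 0 members past the test over all genes and 3 lower adjusted over the list alone (adjusted p = 4.57e-08, and adjusted p = 0.397 with an estimated correlation). The TKO animals were 17.0 ± 1.63 weeks old and the DKO animals 68.0 ± 28.18 weeks (SD, n = 4 each), so genotype and age are not separated. The count of 95 was 276, 40 and 34 without TKO replicate 1, 3 and 4, 149 and 38 without DKO replicate 2 and 3, 36 with limma-voom, 2 with only the 2 groups in the fit, 61 with the lowest 25% of genes left out and 189 with array weights. The call of Trp53 was lost with only the 2 groups (log2 fold change -1.97, adjusted p = 0.622).

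Pieces of one tumour were compared in 5 intact animals with an AP piece and a piece whose code holds DP. No gene of 16468 passed with limma or limma-voom, and 449 had an unadjusted p under 0.05. Ages at collection were compared by exact permutation tests over 6 pairs of groups. Castrated DKO_EP animals were younger than DKO (-32.60 weeks, exact p = 0.00794, adjusted p = 0.0476, n = 5 and 4), with all 5 at 34 to 37 weeks and the DKO animals at 39 to 99 weeks. The difference was -24.20 weeks for DKO_EE against DKO after castration (exact p = 0.143, adjusted p = 0.171), with 43.80 ± 9.36 and 68.00 ± 28.18 weeks (SD, n = 5 and 4). Intact DKO_EE and DKO_EP animals differed by -10.83 weeks (exact p = 0.0182, adjusted p = 0.0545), with 33.50 ± 4.24 and 44.33 ± 6.81 weeks (SD, n = 8 and 3). Without any single animal, the castrated DKO_EP difference ranged from -42.27 to -22.27 weeks and did not pass. With fewer animals the smallest possible exact p is larger, so the lost call says little about how stable the difference is.

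List scores per animal were compared within settings for 8 lists by exact permutation tests. None of 80 tests passed adjustment (smallest adjusted p = 0.289), and 11 had an unadjusted exact p under 0.05. With 20 to 252 assignments of the animals per test, the smallest possible exact p is limited. After adjustment over 80 tests a real difference could hardly pass, so this is no evidence of equal scores. The smallest was for fibroblast genes in castrated DKO_EE against DKO (difference -2.06, exact p = 0.00794). Neuroendocrine scores of the endstage animals ranged from 0.85 to 1.14 in intact DKO, 1.11 to 1.61 in intact DKO_EE, 1.01 to 1.48 in intact DKO_EP, 0.72 to 1.69 in castrated DKO_EE and 1.02 to 1.67 in castrated DKO_EP. In castrated DKO they were 1.12 to 1.32 in 3 animals and -4.63 in replicate 2, which also had the highest Krt5 value, 14.23.

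**Figure D5:**
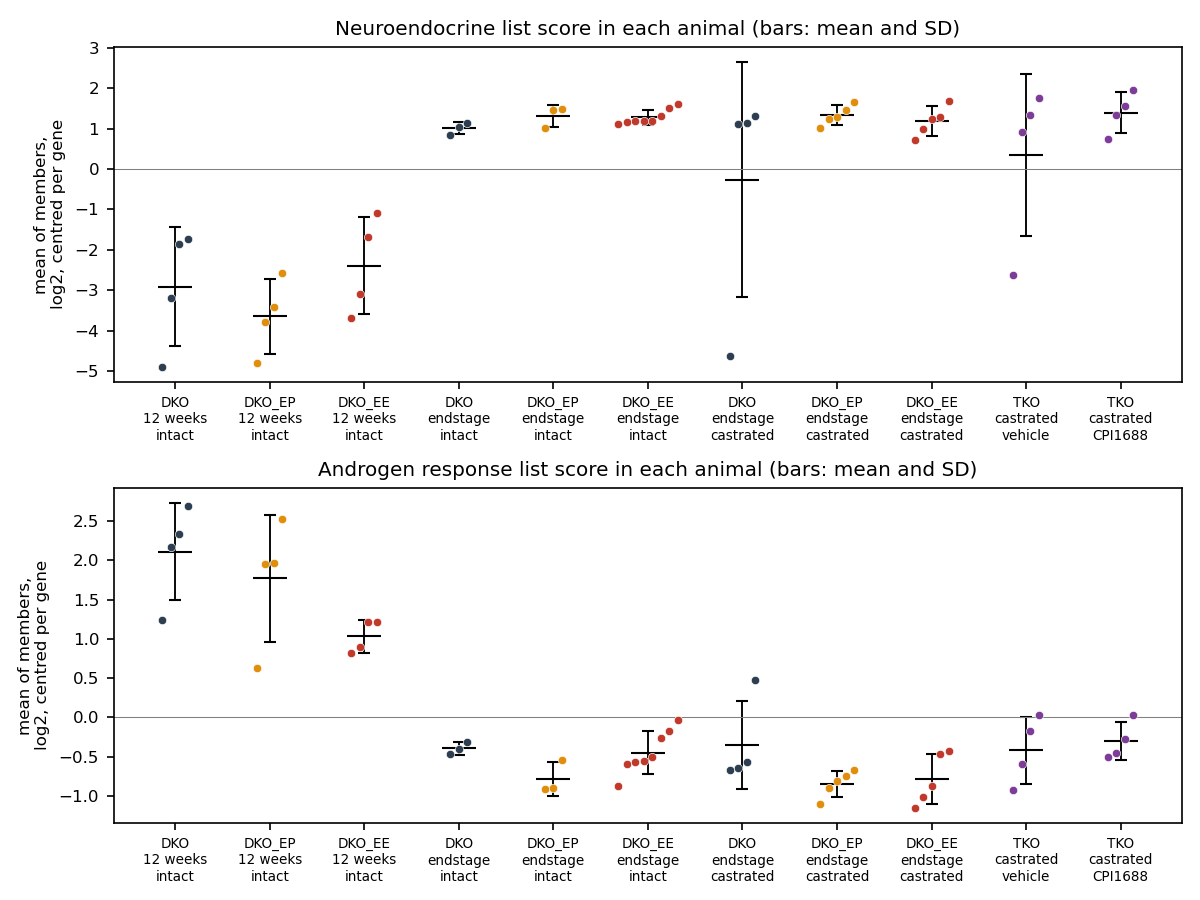
Neuroendocrine and androgen response scores (mean centred log2 value of the list) of each animal in the 11 groups. All endstage DKO_EE and DKO_EP animals lie at 0.72 or more on the neuroendocrine score, and castrated DKO replicate 2 at -4.63.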

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

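The tests of explanations in this part and the counts over other splits of the animals were chosen only after the results they address had been seen, and the interaction tests had been set before.

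Single animals lay far from the others of their group by Dixon's ratio in 11 of 90 groups of 4 to 10 values, where chance gives about 1 in 20 groups. Castrated DKO replicate 2, an animal of 99 weeks, accounts for 6 of them. Its Ezh2 log2 value was 8.43 (next 9.62), its neuroendocrine score -4.63 (next 1.12) and its proliferation score -2.35 (next 0.38). Its androgen response score was 0.48 (next -0.57), its luminal epithelium score 2.24 (next -0.62) and its squamous differentiation score 3.75 (next -0.43). This animal had the highest Krt5 value of its group, 14.23. Castrated DKO_EP replicate 3 had an Ezh2 log2 value of 8.58 (next 9.27) and a basal epithelium score of 0.26 (next -1.40). The others were a luminal epithelium score of 0.00 in castrated DKO_EE replicate 2 (next -0.75), a luminal epithelium score of 2.09 in 12-week DKO_EP replicate 4 (next 1.81) and a proliferation score of 0.31 in intact endstage DKO_EE replicate 4 (next 0.80).

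Genotype effects that differed between settings by an interaction test were few. The DKO_EE effect at intact endstage differed from that at 12 weeks for 21 genes, among them Mybpc1 at 11.97, Lars2 at 7.84, Lhx2 at -5.96, Fign at 4.07, Rora at 2.11 and Pbsn at 5.84. For Mybpc1, a muscle gene, the interaction adds a rise of 6.46 at intact endstage to a 12-week difference of -5.50 (adjusted p = 0.975), where DKO libraries carried more Ttn reads (0.113 to 2.551%) than DKO_EE libraries (0.017% at most), so muscle in the dissection may account for a part. For Pbsn the interaction comes from the 12-week difference alone, since every endstage library of DKO and DKO_EE was listed at 0. For DKO_EP 1 gene differed, Lars2 at 12.06. The share of the reads that Lars2 took differed between pieces of the same animal in intact DKO_EE. No Lars2 interaction can therefore be read as an effect of the genotype. Between castrated and intact endstage, 2 genes differed for DKO_EE, Hist1h4m at 6.20 and Cfap69 at 3.28. For DKO_EP 4 differed, Hist1h4m at 5.79, Cfap69 at 3.51, Lars2 at -10.49 and Traf3 at -1.27. Since both tests share their DKO animals, Hist1h4m and Cfap69 may reflect a difference within DKO. The count of 21 was above the highest of the 99 other splits drawn, 17 (1 of 100 splits as large). That share was not adjusted over the 20 comparisons, so chance was unlikely but not excluded for it. The count of 4 was reached in 2 of 100 splits, but limma-voom called 0 genes, so chance was not excluded for it either. For the counts of 1 and 2, 35 and 15 of 100 splits gave as many, so chance was not excluded. The highest other splits called 112, 1426 and 18 genes for the counts of 1, 2 and 4, and a split that exchanges genotypes in one setting turns a shared genotype effect into an interaction, so these counts do not tell genotype from another structure.

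Castrated and intact endstage tumours differed by 2338 genes in DKO, 2766 in DKO_EE and 1656 in DKO_EP. The highest other splits called 1719, 1318 and 363 (1 of 35, 1 of 100 and 1 of 56 splits as large). These shares are the smallest that the splits allow and were not adjusted over the 20 comparisons, so chance was unlikely but not excluded. A different preparation or counting of the castrated libraries would fit 20 genes. These had at least 10 reads in every intact library and 0 in every castrated one, TKO included. Among them, Mrgpra6 had 5398 to 18899 reads in the intact libraries, Atp5o 215 to 1614 and Ado 147 to 1179. The other way, 2 genes were read in every castrated library and at 0 in every intact one. Such all-or-none values over the 22 castrated libraries argue against castration alone as their cause. For the other genes castration cannot be told apart from a different preparation or counting, since 0 castrated libraries lay in the Rmrp range of the intact ones. Of the 1109 genes called alike in 3 genotypes, 393 did not overlap between any intact and any castrated library.

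Intact endstage DKO_EE and DKO tumours differed by 277 genes, and the highest other split called 132 (1 of 100 as large), so chance was excluded. The median change of these genes in their called direction was 1.67 (median SE 0.32). It was 1.59 in libraries with Lars2 under 10% of reads (SE 0.36, 94 calls, 75 of them shared) and 1.57 with Lars2 as a covariate (SE 0.46, 6 calls, all shared). With age as a covariate it was 1.70 (SE 0.37, 81 calls, 76 shared) and with the adipocyte score 1.5 (SE 0.39, 64 calls, 62 shared). For these genes this argues against each as the whole cause. The genes were picked by their calls in the same animals, which favours kept sizes, so a share of each is not excluded. The calls ended with standard errors raised by the covariates and by fewer libraries, whose shares were not separated. An effect of the genotype would fit, since 80 genes were called in the same direction in the castrated animals, where the 277 genes had a median change of 0.90 and 241 kept their direction. With the identifier letters as a covariate, 266 genes passed and 236 of the 277 were shared, and genotype remains a hypothesis, since it was found and tested on the same data with 3 DKO animals.

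Castrated DKO_EE and DKO tumours differed by 1278 genes, and the highest other split called 110 (1 of 100 as large), so chance was excluded. The median change in the called direction was 1.92 (median SE 0.43). It was 1.74 without the 99-week animal (SE 0.40, 979 of the calls shared) and 1.66 with age as a covariate (SE 0.50, 379 shared). For these genes this argues against either as the whole cause. The genes were picked by their calls in the same animals, which favours kept sizes, so a share of either is not excluded. The mean change of the neuroendocrine list went from 1.49 to 0 without the 99-week animal. With the fibroblast score as a covariate, the median of the 566 higher genes went from 1.65 (SE 0.36) to 1.59 (SE 0.73, 17 calls shared). Their sizes thus held, but the score itself differed between the genotypes (-1.75 ± 0.49 in DKO_EE and 0.31 ± 0.58 in DKO). The covariate and the genotype are therefore only partly separated, and a share of fibroblasts is not excluded. The 712 lower genes went from 1.99 (SE 0.45) to 1.25 (SE 0.86), so a loss of stroma and a loss of expression cannot be told apart for them. That covariate left 27 calls, and the other calls ended with smaller changes of the lower genes as well as larger standard errors. The genotype may explain a part, since 89% of the genes had the same direction in the intact animals, while identifier letters and genotype coincide in the castrated animals.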

How the results depend on the processing

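Limma-voom, the settings by Lars2 or Ttn, the adjustments for list scores and leaving out intact DKO_EE animals were chosen only after the results were seen, and the other alternatives were set before. The edgeR alternative had been planned only for a table of raw counts and was not run, and limma-voom on the recovered reads was the count method used. No paired analysis was possible because the replicate numbers of different groups mark different animals. Of 734 values that answer a comparison, 575 were labelled the same, 126 counts or values moved, 6 became called and 27 lost a call. For a tested value, the same means a kept direction and side of the threshold. A count of called genes has neither, and was labelled the same when it stayed near its main count without having to equal it. The 575 can thus include counts that changed, so they do not measure how stable the counts are. For the gene lists, 1437 of 1667 values stayed, 23 moved, 6 reversed, 30 became called and 171 lost a call, of which 67 of 88 list results with an estimated correlation. For named genes, 9638 of 10780 stayed, 85 moved, 165 became called and 892 lost a call. With 3687048 reads in the smallest library, differences among genes with few reads rest on counting error as well. In castrated DKO_EE against DKO, 38.8% of simulated 2-fold changes were recovered, all in genes above a minimum mean count. For all values below, the cause was not tested unless fewer animals or a covariate is named.

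With array weights, the counts were 1308 (intact) and 2407 (castrated) for DKO_EE against DKO, 26 and 57 for DKO_EP against DKO, 1430 and 1079 for DKO_EE against DKO_EP, 3679 and 3577 for castrated against intact DKO and DKO_EP, 189 for TKO against DKO, 614, 10, 26 and 29 for the 4 interactions, and 519 shared genes. Ezh2 was -1.31 (adjusted p = 0.0018) in castrated DKO_EE against DKO and -0.90 (0.0137) against DKO_EP.

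Age as a covariate gave 81 (intact) and 454 (castrated) for DKO_EE against DKO, 0 for castrated DKO_EP against DKO, 16 for intact DKO_EE against DKO_EP and 22 shared genes, with Ezh2 at -1.31 (adjusted p = 0.0683) and -1.07 (0.39) in intact DKO_EE against DKO and DKO_EP. The neuroendocrine list reversed for castrated DKO_EE (0.738) and DKO_EP (0.0427) against DKO. Identifier letters as a covariate gave Ezh2 at 0.04 in DKO_EP against DKO at 12 weeks.

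Lars2 as a covariate gave 6 for intact DKO_EE against DKO and 171 against DKO_EP, with Ezh2 at -1.07 (0.184), -1.27 (0.0595) and, in DKO_EP against DKO, 0.19. Libraries under 10% Lars2 gave 94 and Ezh2 at -1.32 (0.0548) for DKO_EE against DKO, and those over 10% gave 118 and -1.30 (0.0959) for DKO_EE against DKO_EP. Animals with Ttn under 1% gave 10 and 6 for DKO_EE and DKO_EP against DKO at 12 weeks, with Ezh2 at 0.15 in DKO_EP, and reversed the neuroendocrine list in DKO_EE against DKO (0.0485) and the skeletal muscle list in DKO_EE against DKO_EP (0.0366).

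All 11 groups in one fit gave 84, 4 and 1 at 12 weeks (DKO_EE and DKO_EP against DKO, DKO_EE against DKO_EP), 3 and 45 for intact and castrated DKO_EP against DKO, and Ezh2 at -0.90 (0.0384) in castrated DKO_EE. Only the 2 groups gave 473 for castrated DKO_EE against DKO, 3 and 0 for intact and castrated DKO_EP against DKO, 787 for castrated DKO_EE against DKO_EP, 990 for castrated against intact DKO, 2 for TKO against DKO, 33 shared genes, and Ezh2 at -1.12 (0.0583) in intact DKO_EE against DKO_EP.

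The first library of each animal gave 116 for intact DKO_EE against DKO and Ezh2 at -1.27 (0.0878), and at -1.09 (0.117) against DKO_EP. Libraries with duplicateCorrelation gave 2 for intact DKO_EP against DKO and 571 for DKO_EE against DKO_EP. Only pure AP and DP codes gave Ezh2 at -0.06 between pieces. A larger offset gave 9 for castrated DKO_EP against DKO and 0 for the DKO_EE castration interaction. The lowest 25% of genes left out gave 61 for TKO against DKO, and 9 and 4 for the DKO_EE interactions. Quantile normalization gave 2 for the DKO_EP castration interaction. Limma-voom gave 2 for castrated DKO_EP against DKO, 36 for TKO against DKO, 32 and 2 for the interactions with 12 weeks and 0 for the DKO_EP castration interaction.

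Leaving out single animals, counts ranged for DKO_EE against DKO from 0 to 5 at 12 weeks (5 without DKO replicate 4), 64 to 590 at intact endstage (74, 121 and 64 without DKO replicates 1, 2 and 3, 161, 491, 590, 134 and 179 without DKO_EE replicates 2, 3, 4, 5_6 and 7_8) and 780 to 1796 at castrated endstage (780, 829 and 787 without DKO_EE replicates 1, 2 and 5, 783 without DKO replicate 1). For DKO_EP against DKO they ranged from 0 to 5 at 12 weeks (5 without DKO replicate 4), 0 to 1 at intact endstage (1 without DKO replicate 3) and 4 to 67 at castrated endstage (10, 15, 67 and 9 without DKO replicates 1 to 4). DKO_EE against DKO_EP gave 47 to 602 at intact endstage (168, 91 and 47 without DKO_EP replicates 1_2, 3_4 and 5, 602, 496 and 175 without DKO_EE replicates 3, 4 and 5_6) and 166 to 248 at castrated endstage (181 without DKO_EE replicate 3, 180, 167 and 166 without DKO_EP replicates 1 to 3). TKO against DKO gave 34 to 276 (276, 40 and 34 without TKO replicates 1, 3 and 4, 149 and 38 without DKO replicates 2 and 3), and shared genes 26 to 144 (29, 31 and 26 without intact DKO replicates 1 to 3, 49 without castrated DKO replicate 1, 141, 144 and 46 without intact DKO_EE replicates 3, 4 and 5_6). The interactions with 12 weeks gave 15 to 51 for DKO_EE and 1 to 3 for DKO_EP (42 and 3 without 12-week DKO replicate 4, 51 without intact DKO_EE replicate 3), and those with castration 0 to 5 for DKO_EE and 0 to 4 for DKO_EP.

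Ezh2 ranged from -1.41 to -1.20 in intact and -1.21 to -0.78 in castrated DKO_EE against DKO, -1.19 to -0.99 in intact DKO_EE against DKO_EP (calls lost without DKO_EE replicates 1, 7_8 and 11_12), -0.37 to 0.06 in castrated against intact DKO (0.06 without castrated DKO replicate 2) and -0.23 to 0.42 in TKO against DKO (-0.16 without TKO replicate 4, -0.23 without DKO replicate 2). Age differences ranged from -42.27 to -22.27 weeks for castrated DKO_EP against DKO and 4.6 to 10.6 for DKO_EE against DKO_EP (10.6 without DKO_EE replicate 1). The neuroendocrine list reversed in 12-week DKO_EE against DKO without DKO replicate 4 (0.977, range 1.51e-06 to 0.977) and in CPI1688 against vehicle without vehicle replicate 1 (0.458, range 7.6e-11 to 0.458).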

Other observations

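The tests in this part were chosen only after the endstage results were seen, and those of the shared genes at 12 weeks and with CPI1688 were written down before their own values were looked at.

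Near Trp53 on chromosome 11, genes of the inflammasome family were lower in TKO tumours given vehicle than in castrated DKO tumours (n = 4 each, limma). Nlrp1b, an inflammasome sensor gene, had a log2 fold change of -2.96 (SE 0.59, adjusted p = 0.00772), its neighbour Nlrp1a of -1.86 (SE 0.43, adjusted p = 0.0287) and the pseudogene Nlrp1c-ps of -5.05 (SE 0.49, adjusted p = 1.13e-08). Xaf1, an apoptosis factor gene nearby, had 2.12 (SE 0.50, adjusted p = 0.0349) and Atp1b2, which adjoins Trp53, 2.13 (SE 0.52, adjusted p = 0.0441). The Nlrp1 copies resemble one another, so their reads are uncertain. Nlrp1b lost its call without TKO replicate 3 (adjusted p = 0.0779) or 4 (0.0509). These genes were singled out after their values were seen.

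Whether a stretch of chromosome was carried along with an engineered Trp53 allele cannot be told. Within 5 megabases of Trp53, 6 of 170 genes were called (3.53%) against 88 of 16579 elsewhere (0.531%; one-sided Fisher's exact test, p = 0.00039), but the window was chosen after these genes were seen, and without the 3 Nlrp1 copies 3 of 167 were called (1.8%, p = 0.0627). The labels give neither the strains nor the alleles. Around Ezh2, 1.37% of the genes were called in castrated DKO_EE against DKO (1 of 73, Zfp282), below the 7.75% elsewhere. At intact endstage 0 of 75 were called, against 1.67% elsewhere. A stretch that alters few genes need not exceed a broad change elsewhere, so these shares do not decide whether one lies there. The TKO comparison itself called 95 genes, and 14 of 35 splits of the animals gave as many, with 3308 in the highest other split, which points to a structure of the samples.

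The 80 genes called in DKO_EE at both endstages were followed into other groups as a hypothesis that they answer to Ezh2 directly. In 12-week DKO_EE tissue their score, counted in the endstage direction, differed from DKO by -0.16 (exact p = 0.171, adjusted p = 0.343, n = 4 each), with 35 of 79 genes in that direction, and in 12-week DKO_EP tissue by -0.20 (exact p = 0.314, adjusted p = 0.4). With CPI1688 the score was higher than with vehicle by 0.51 (exact p = 0.171, adjusted p = 0.343, n = 4 each), with 57 of 80 genes in that direction and 2 of 4 animals above all vehicle animals. None of these passed, so the hypothesis stays open.

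Among the Hox genes, the rise in castrated DKO_EE tumours was seen in 4 of 9 Hoxd genes and in 0 of 26 others (one-sided Fisher's exact test, p = 0.00241). This grouping was chosen after the 4 genes had been seen and neighbouring genes are not independent, so the test decides nothing. In castrated DKO_EP tumours, where Ezh2 lay near DKO (-0.19), Hoxd8, Hoxd3 and Hoxd9 were also above DKO by 2.89, 2.21 and 2.11 (limma, adjusted p = 0.118, 0.185 and 0.244, n = 5 and 4), so whether the rise follows the Ezh2 level stays open. The same 4 genes scored higher by 1.74 in intact endstage DKO_EE than in DKO (exact p = 0.0121, adjusted p = 0.0727, n = 8 and 3, 7 of 8 animals above all DKO animals). The difference was 0.55 at 12 weeks and 0.91 with CPI1688 (exact p = 0.4 each, n = 4 per group), so neither passed.

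Other splits of the animals were counted for the remaining comparisons. Chance was unlikely for DKO intact endstage against 12 weeks (6163 genes, highest other 3343, 1 of 35 splits as large). The same held for DKO_EE against DKO_EP at intact endstage (271, highest other 53, 1 of 100) and castrated endstage (281, highest other 1, 1 of 100). It was not excluded for them, since these shares were not adjusted over the 20 comparisons. For DKO_EP against DKO after castration the count of 5 was above the highest other, 2 (1 of 100). But limma-voom called 1 gene higher and 1 lower, and no gene passed with age as a covariate. This count is small and its share was not adjusted over the 20 comparisons, so chance was not excluded for it. No gene passed at 12 weeks or with CPI1688 by limma, so all 35 of 35 splits gave as many, with highest other counts of 2 for DKO_EE against DKO, 215 for DKO_EP against DKO, 42 for DKO_EE against DKO_EP and 1094 for CPI1688. The counts of 215 and 1094 point to a structure of the samples other than the groups. For DKO_EP against DKO at intact endstage (0 genes, highest other 7, 10 of 10 splits) and for the AP against DP-containing pieces (0 genes, highest other 0, 16 of 16 splits), every split reaches a count of 0. The splits were also too few for a share under 0.05.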
